A study of Mus musculus with 9 samples.

How the data were processed

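Targeted bisulfite sequencing was analysed in 9 libraries of primary cardiomyocytes from ventricles of CD-1 mouse embryos at embryonic day 13.5. Sodium bisulfite converts unmethylated cytosines so that they are read as T, whereas methylated cytosines are still read as C. Per the labels' protocols, cells were cultured for 48 h, transfected with 0.012 pmol of siRNA against DNMT3a, of siRNA against DNMT3b or of a negative control siRNA, and collected 72 h later. Cardiomyocytes were then enriched magnetically with an antibody to VCAM1, a surface protein of these cells. Primers for 2 promoter regions of each of 15 genes were used on the converted DNA, and the products of one DNA sample were pooled, tagmented and sequenced on a MiSeq.

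FastQC, Bismark and Bowtie2 and the mouse build mm10 are named in the submitters' processing notes. Their versions and settings were not given in the sources used here. Each deposited file lists cytosines by region name, offset within the region and sequence context. Per the file headers, the deposited values are the coverage of each cytosine as a count of reads, and the percent of those reads carrying C and the percent carrying T. The reads carrying C were recovered as coverage times percent. All 23884 of 23884 values with coverage came out whole within 0.01 reads, so these products were used as methylated counts.

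The files give no chromosome coordinate for the regions. Offsets are therefore given as listed, and the position of a gene is that of the annotation of GRCm38.p6, the assembly that mm10 corresponds to. All 15 gene symbols were matched in it. Before the data were examined, a region had been defined as a run of sites with no gap over 200 bp, assigned to the nearest target gene. The files name the regions, and the largest gap between listed cytosines was 49 bp, so the names were used instead.

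The files list 3063 cytosines in 30 regions, of which 355 are CpG, 791 CHG and 1917 CHH. No reads were recorded in 4 regions, Cdkn1a_2, Cdkn1b_2, Cdkn1c_2 and Mef2c_2, which hold 35 CpG sites. Of the 320 CpG sites in the other 26 regions, 310 had at least 30 reads in each library and were tested, and 10 were left out. Of the 90 and 94 cytosines listed for Mef2d_1 and Mef2d_2, 24 match in context at a single shift of their offsets. These 2 regions may therefore overlap. Some of their CpG sites may be counted in both, which no count or test here corrects. The summed coverage of a library was 27193672 to 32543683 cytosine calls, and the median coverage of a tested CpG was 7964 reads. PCR reads without molecular identifiers are not independent molecules, so these counts describe counting error only. Errors of levels are SDs between libraries, and those of log2 odds ratios are standard errors.

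The level of a site is its percent of reads carrying C, and the level of a region is the mean over its tested CpG sites. Sites and regions were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on methylated and unmethylated counts, with a coefficient for each library and all 9 libraries in a single fit. Tests were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a call needed an adjusted p under 0.05. For regions, the counts of the tested sites were summed. Changes are given as log2 odds ratios with standard errors. The mean over all regions and the means over 4 gene groups were compared by exact two-sided permutation tests, which with 3 against 3 libraries cannot give a p below 0.10. The gene groups were sarcomere genes (Myh6, Myh7, Myh7b, Tnnc1, Tnni3, Tnnt2), natriuretic peptide genes (Nppa, Nppb), CDK inhibitor genes (Cdkn1a, Cdkn1b, Cdkn1c) and transcription factor genes (Camta1, Camta2, Mef2c, Mef2d). Exact p-values were adjusted over the 4 groups.

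All target genes are named with their regions. Sites were to be named where they passed the test without overlap between groups. Where no site passed, the 3 sites with the smallest unadjusted p in a comparison are given as not passing. Any other site that is named was chosen after its values were seen. The groups, tests, gene groups, naming rule, coverage minimum and the alternative settings below, apart from those said to be added, were set before the data were examined.

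The alternatives were coverage minimums of 10 and 100, limma 3.58.1 on the log2 ratio of methylated to unmethylated counts with a prior count of 2, a quasi-binomial model and DESeq2 1.42.0. Others were a fit to the 6 libraries compared, a fit with the replicate number as a block, a minimum difference of 5 points, sites between 2% and 98%, and leaving out each library. Means were also recomputed with reads pooled over a region and with sites weighted equally. DESeq2 on regions, and means without Myh7b_1 or without sites of wide spread, and paired differences of gene group means were added after seeing the data.

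The tests were tested on simulated data with the coverage, levels and spread of the 310 sites, in the design of DNMT3a against negative siRNA, in 5 simulations of 60 changed sites for each size of change. False calls are given over all 5. At a log2 odds ratio of 0.5, edgeR recovered 0.333% of the changed sites and DESeq2 17.7%, with 1 of 2 and 9 of 62 calls false. At 1 they recovered 45.7% and 53.7%, with 10 of 147 and 23 of 184 calls false. At 2 they recovered 74.0% and 80.7%, with 6 of 228 and 16 of 258 calls false. Group means and figures were computed with the Python packages numpy, pandas and matplotlib.

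The titles number the libraries of each group from 1 to 3. Nothing in the labels says how libraries relate beyond that, and the growth protocol says that the ventricular tissue of each litter was pooled, so p-values measure the spread between these libraries, which may be technical. A check for libraries deposited more than once found none within a group that agreed within sampling noise (chi-square per site 14.9 to 91.0). This does not show that libraries came from separate cultures.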

Results

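Methylation of cytosines in CpG dinucleotides was measured at promoter regions of 15 genes of the heart and of the cell cycle. The study asked which of these regions differ in methylation after knockdown of DNMT3a or DNMT3b, the enzymes that place methyl groups on previously unmethylated CpG sites. There were 3 libraries each of negative, DNMT3a and DNMT3b siRNA. Neither Dnmt3a nor Dnmt3b was among the amplified genes, so the degree of knockdown was not analysed here. Summed coverage was 28535010 to 30927206 cytosine calls per library in negative siRNA, 29309729 to 32543683 in DNMT3a siRNA and 27193672 to 31839328 in DNMT3b siRNA. Of reads at cytosines outside CpG, 0.197% ± 0.018 carried C in negative siRNA, 0.208% ± 0.030 in DNMT3a siRNA and 0.189% ± 0.0019 in DNMT3b siRNA (SD, n = 3 each), which bounds incomplete conversion.

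The promoter regions covered the whole range of methylation in negative siRNA libraries (mean ± SD, n = 3 throughout). Among sarcomere genes, Tnnc1 encodes cardiac troponin C, and its regions stood at 90.5% ± 0.80 and 40.3% ± 0.27. Tnnt2 encodes cardiac troponin T, at 56.6% ± 3.65 and 83.9% ± 0.49, and Tnni3 encodes cardiac troponin I, at 54.8% ± 2.74 and 63.3% ± 1.37. The myosin heavy chain genes Myh6 and Myh7 encode the alpha and beta chains. The regions of Myh6 were at 47.8% ± 0.41 and 70.7% ± 1.05, and those of Myh7 at 59.6% ± 2.35 and 8.76% ± 1.13. The related Myh7b was at 29.3% ± 11.9 in its first region, with the widest spread, and at 42.6% ± 0.74 in its second. Tnnt2 lies on chromosome 1 at 135836315 to 135852268, and Myh7 on chromosome 14 at 54970684 to 54994626. Myh7b lies on chromosome 2 at 155611243 to 155634307.

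Nppa and Nppb, neighbours on chromosome 4, encode the atrial and brain natriuretic peptides. Nppa (148000722 to 148002074) was methylated at 43.1% ± 4.92 and 8.95% ± 2.15 in its regions, and Nppb (147985786 to 147987205) at 4.32% ± 0.76 and 56.5% ± 4.56. Among the CDK inhibitor genes, which restrain the cell cycle, Cdkn1a (p21) was at 60.3% ± 1.86 and Cdkn1b (p27) at 0.287% ± 0.0057. Cdkn1c (p57), an imprinted gene on chromosome 7 at 143458339 to 143461059, was at 23.2% ± 2.95. Of the transcription factor genes, the calmodulin-binding factors Camta1 (0.226% ± 0.043 and 0.179% ± 0.058) and Camta2 in its first region (0.226% ± 0.031) were nearly unmethylated. The second region of Camta2 was at 13.1% ± 0.54. The myocyte enhancer factor gene Mef2c was at 82.0% ± 1.44, and Mef2d, on chromosome 3 at 88141941 to 88172091, at 2.25% ± 0.63 and 16.0% ± 1.07.

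**Figure D1:**
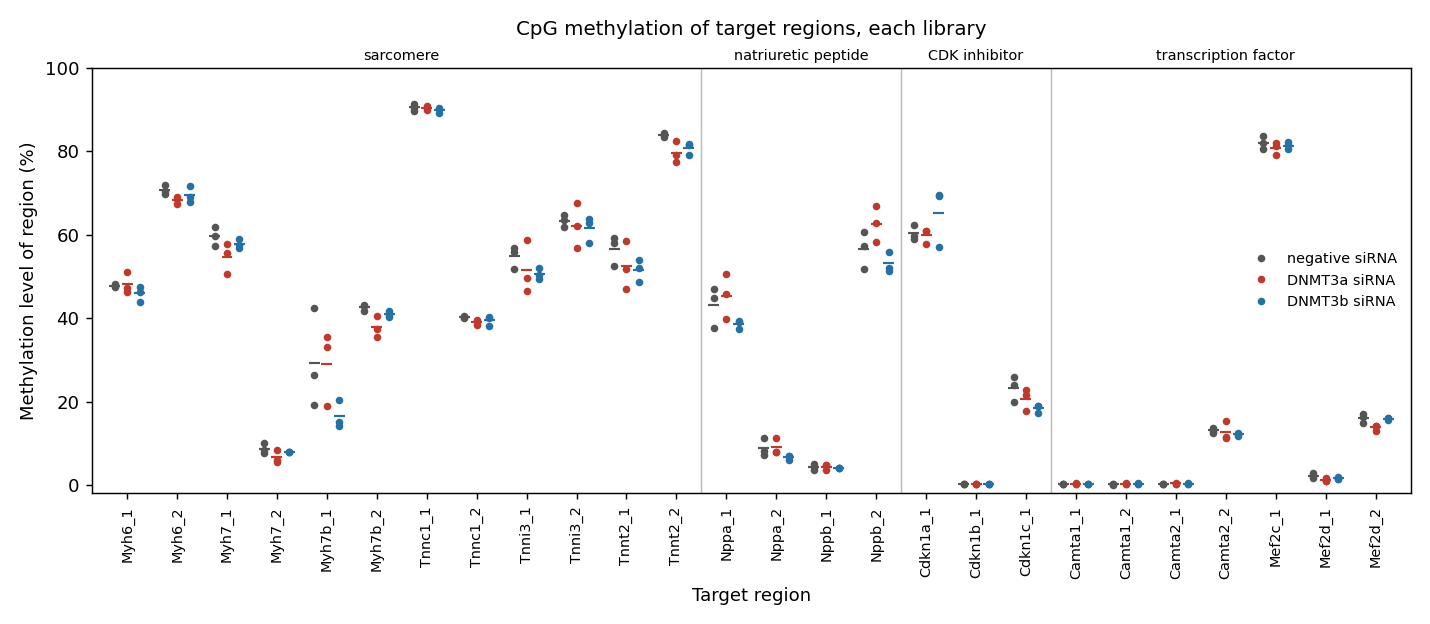
Methylation level (percent, vertical axis) of the 26 regions with reads, ordered by gene group along the horizontal axis; points are single libraries of negative, DNMT3a and DNMT3b siRNA and short lines are group means (n = 3). Levels differ far more between regions than between siRNA groups, and Myh7b_1 spreads most among negative and among DNMT3a siRNA libraries.

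The comparison of DNMT3a siRNA with negative siRNA asked which promoters lose or gain methylation when DNMT3a is targeted. Mean levels were lower in 17 of 26 regions, and sarcomere genes accounted for 11 of these 17, but no region or site passed the main edgeR test. The mean over regions was 35.8% ± 1.85 with DNMT3a siRNA and 36.9% ± 0.83 with negative siRNA, a difference of -1.06 points (exact two-sided permutation p = 0.40, n = 3 each, smallest possible p 0.10). The lowest p-values among regions belonged to Tnnt2_2, at 79.6% ± 2.50 against 83.9% ± 0.49, Myh7b_2, at 37.8% ± 2.55 against 42.6% ± 0.74, and Mef2d_2, at 13.9% ± 0.67 against 16.0% ± 1.07. In each of these the 3 DNMT3a libraries lay below all 3 negative ones, and edgeR's adjusted p was 0.117.

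With edgeR, 0 of 310 sites and 0 of 26 regions were called, while 36 sites (22 lower, 14 higher) and 3 regions had an unadjusted p under 0.05. Of the 36, 18 lower and 3 higher sites had mean levels between 2% and 98%. The other 11 higher sites, 9 of them in Camta2_1, differed by 0.099 to 0.46 points. Without negative siRNA replicate 1 there were 21 such sites, while such regions numbered 8 without DNMT3a siRNA replicate 2 and 5 without DNMT3a siRNA replicate 3. The counts of sites called by other tools were 0 with limma, 0 with the quasi-binomial model and 4 with DESeq2, all lower. The DESeq2 sites were offset 94 of Tnnt2_1 and offset 225 of Myh7_2, described next, and offset 209 of Tnnt2_2 and offset 195 of Mef2d_2, named after their values were seen. Groups did not overlap at 47 sites and 6 regions, or 15.2% and 23.1%, where chance gives 10% on average. Sites of an amplicon are not independent, and these shares were not tested against 10%. The sites with the smallest p did not pass after edgeR's adjustment over the 310 sites. With only the 177 sites between 2% and 98% tested, edgeR called 2 of them, those of Tnnt2_1 and Myh7_2 (adjusted p = 0.0183 and 0.0293). The CpG at offset 94 of Tnnt2_1 was at 84.3% ± 2.02 against 91.5% ± 0.65 (log2 odds ratio -0.99 ± 0.18 SE, adjusted p = 0.130, 8688 to 13152 reads). The CpG at offset 225 of Myh7_2 was at 8.06% ± 0.49 against 12.8% ± 1.08 (-0.74 ± 0.16 SE, adjusted p = 0.174, 5311 to 6994 reads), and that at offset 341 of Mef2d_2 at 2.52% ± 0.38 against 4.10% ± 0.37 (-0.74 ± 0.19 SE, adjusted p = 0.343, 1116 to 2364 reads).

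Among sarcomere genes, 61 of 71 sites and 11 of 12 regions were lower in mean with DNMT3a siRNA, and the group mean was 51.6% ± 2.67 against 54.0% ± 0.77 (exact permutation p = 0.30, adjusted p = 0.40 over the 4 groups). Adjusted over the list alone, edgeR called 2 sarcomere sites, those of Tnnt2_1 and Myh7_2 above, both lower (smallest adjusted p 0.0299), against 0 when adjusted over all sites. The natriuretic peptide genes had a group mean of 30.4% ± 3.02 against 28.2% ± 2.81 (exact permutation p = 0.40). Nppb_2, at 62.6% ± 4.33 against 56.5% ± 4.56, was higher in mean by 6.08 points, or 3.66 without negative siRNA replicate 2 and 3.97 without DNMT3a siRNA replicate 2. Nppa_1 differed by 2.26 points, with its sign not kept without negative siRNA replicate 2 (-0.52) or DNMT3a siRNA replicate 2 (-0.34), and up to 5.06 points without other libraries. Nppa_2 and Nppb_1 differed by only 0.086 and 0.067 points, and the log2 odds ratio of Nppa_2 was -0.01. CDK inhibitor genes averaged 26.9% ± 0.91 against 27.9% ± 1.44 (exact permutation p = 0.40), with 61 of 80 sites lower in mean. Of these 80 sites, 52 lay in the single amplicon Cdkn1c_1, at 20.7% ± 2.56 against 23.2% ± 2.95, so the count rests mostly on it. Another 23 lay in Cdkn1b_1, at 0.288% against 0.287%. Their direction cannot be told from incomplete conversion. The difference of -1.01 points in the mean of CDK inhibitor genes was -0.24 points without negative siRNA replicate 1, -1.54 without DNMT3a siRNA replicate 2 and -1.66 without negative siRNA replicate 3. Transcription factor genes averaged 15.6% ± 0.42 against 16.3% ± 0.45 (exact permutation p = 0.30), with 55 of 126 sites lower. Of these 126 sites, 43 lay in Camta1_1, 8 in Camta1_2 and 34 in Camta2_1, regions with group means of 0.18% to 0.39%. That is near the 0.197% and 0.208% of reads carrying C outside CpG, so the direction of these sites cannot be told from incomplete conversion. In these 3 groups 0 sites were called when adjusted over the list alone.

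The library of DNMT3a siRNA replicate 2 stood apart, with a mean over regions of 38.0% where replicates 1 and 3 had 34.8% and 34.7%. Without it edgeR called 3 regions, Myh7_2, Myh7b_2 and Tnnt2_2, all lower (adjusted p = 0.0165), and the difference was -2.12 points in the mean over regions, -3.90 points in sarcomere genes and 0.61 points in natriuretic peptide genes. Without negative siRNA replicate 2 the last was 0.51 points, and without DNMT3a siRNA replicate 3 it was 3.63 points. Leaving out DNMT3a siRNA replicates 1 and 3 in turn instead brought the mean over regions nearer to negative siRNA (-0.57 and -0.49 points), and sarcomere genes likewise (-1.48 and -1.73 points). DESeq2 on regions, chosen after seeing the data, called Mef2d_2, Myh7b_2 and Tnnt2_2.

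**Figure D2:**
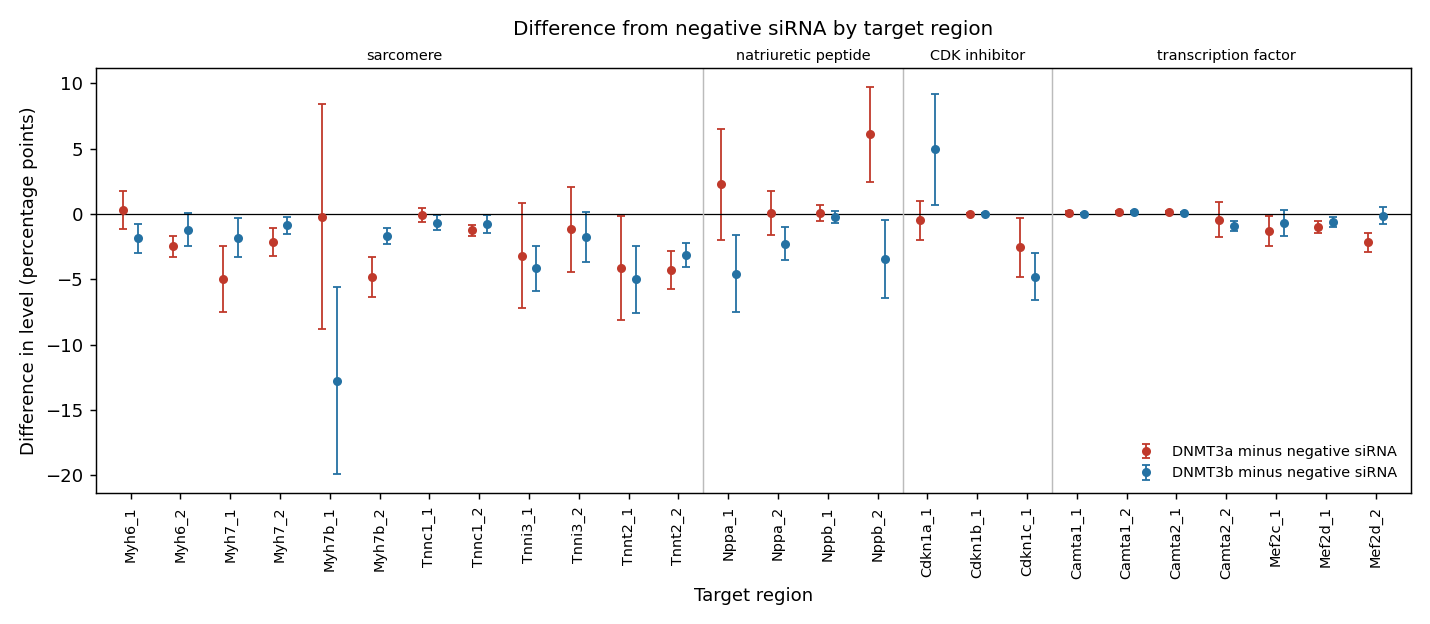
Difference in methylation level from negative siRNA (percentage points, vertical axis) for each region; points are differences of group means and bars are the standard error from the SDs of 3 libraries per group. Most sarcomere regions lie below 0 with either siRNA, and the natriuretic peptide regions lie below 0 with DNMT3b siRNA, whereas with DNMT3a siRNA 2 of them lie above 0 and 2 near it.

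The same question was asked of DNMT3b siRNA. Mean levels were lower than with negative siRNA in 21 of 26 regions, including all 12 sarcomere regions and all 4 natriuretic peptide regions, although no region or site passed the test. The mean over regions was 35.0% ± 0.27 against 36.9% ± 0.83, a difference of -1.86 points. All 3 DNMT3b libraries lay below all 3 negative libraries, which gives the smallest p the design allows (exact two-sided permutation p = 0.10, n = 3 each). Tnnt2_2 was at 80.8% ± 1.53 against 83.9% ± 0.49 (edgeR adjusted p = 0.434) and Cdkn1c_1 at 18.4% ± 1.06 against 23.2% ± 2.95 (adjusted p = 0.434), both without overlap. Myh7b_1 was at 16.6% ± 3.39 against 29.3% ± 11.9, with overlapping groups, and its log2 odds ratio of -1.59 was -0.96 without negative siRNA replicate 1.

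With edgeR, 0 of 310 sites and 0 of 26 regions were called, while 29 sites (26 lower, 3 higher) and 2 regions had an unadjusted p under 0.05. The number of such sites was 10 without negative siRNA replicate 1, 40 without negative siRNA replicate 3, 16 without DNMT3b siRNA replicate 2 and 12 without DNMT3b siRNA replicate 3. Over single libraries left out, such regions numbered 0 to 3, with 0 without negative siRNA replicate 1 or DNMT3b siRNA replicate 3. The counts of sites called were also 0 with limma, with the quasi-binomial model and with DESeq2. Groups did not overlap at 64 sites and 5 regions, or 20.6% and 19.2%, where chance gives 10% on average, and 57 of the 64 sites were lower. Many of the 64 lay in the single amplicon Cdkn1c_1, and sites of an amplicon are not independent. The share was not tested against 10%. Of the 29 sites, 21 lay in CDK inhibitor genes. The 20 lower ones were all in the single amplicon Cdkn1c_1, and the remaining site, in Cdkn1b_1, was higher. The sites with the smallest p did not pass after adjustment by edgeR (adjusted p = 0.503 for each). The CpG at offset 237 of Cdkn1c_1 was at 8.30% ± 0.23 against 13.1% ± 2.40 (log2 odds ratio -0.73 ± 0.21 SE, 3105 to 7714 reads). The CpG at offset 195 of the same region was at 5.08% ± 1.63 against 9.32% ± 1.90 (-0.96 ± 0.28 SE, 882 to 2067 reads), and that at offset 26 of Nppa_2 at 6.28% ± 0.60 against 10.9% ± 1.55 (-0.86 ± 0.25 SE, 1395 to 2119 reads).

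Sarcomere genes averaged 51.0% ± 0.43 with DNMT3b siRNA against 54.0% ± 0.77, with 67 of 71 sites lower in mean (exact permutation p = 0.10, adjusted p = 0.40 over the 4 groups). Natriuretic peptide genes averaged 25.6% ± 0.86 against 28.2% ± 2.81, with 28 of 33 sites lower in mean (exact permutation p = 0.30). Their difference of -2.64 points was -4.25 without negative siRNA replicate 2 and -1.68 without negative siRNA replicate 3. CDK inhibitor genes averaged 28.0% ± 2.23 against 27.9% ± 1.44 (exact permutation p = 0.90). There the lower mean of Cdkn1c_1 was offset by Cdkn1a_1, which was at 65.2% ± 7.11 against 60.3% ± 1.86 (2.79 to 9.04 points higher over single libraries left out). With sites weighted equally the difference for CDK inhibitor genes was -2.81 points (exact permutation p = 0.10), since Cdkn1c_1 holds 52 of the 80 sites. Transcription factor genes averaged 16.0% ± 0.078 against 16.3% ± 0.45 (exact permutation p = 0.30). Adjusted over the list alone, edgeR called 0 sites in each of the 4 groups, as it did over all sites.

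DNMT3a and DNMT3b siRNA were also compared directly, to see where the knockdowns differ from each other. The largest difference in a single region was at Myh7b_1, at 29.1% ± 8.89 with DNMT3a siRNA and 16.6% ± 3.39 with DNMT3b siRNA, with overlapping groups (edgeR adjusted p = 0.269). It rested largely on offset 145, at 40.1% ± 22.0 against 7.37% ± 10.3, named after its values were seen. The adjusted p of that site was 0.482 with edgeR and 0.0163 with DESeq2. Among the means of the 4 gene groups, natriuretic peptide genes differed most. Their mean was 30.4% ± 3.02 with DNMT3a siRNA and 25.6% ± 0.86 with DNMT3b siRNA, a difference of 4.76 points with no overlap (exact two-sided permutation p = 0.10, the smallest possible, adjusted p = 0.40 over the 4 groups). All 4 of their regions and 26 of 33 sites were higher in mean with DNMT3a siRNA, although sites within Nppb_2 went in both directions. Nppb_2 was at 62.6% ± 4.33 against 53.1% ± 2.45 (edgeR adjusted p = 0.269) and Nppa_1 at 45.4% ± 5.41 against 38.6% ± 1.11 (adjusted p = 0.518), so neither passed the test. Among regions the lowest p-values by edgeR belonged to Nppb_2, the sarcomere region Myh6_1 and Myh7b_1. Myh6_1 was at 48.1% ± 2.50 against 45.9% ± 1.85, with overlapping groups (edgeR adjusted p = 0.269). The difference of 6.82 points at Nppa_1 was 4.22 without DNMT3a siRNA replicate 2.

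With edgeR, 0 of 310 sites and 0 of 26 regions were called, while 24 sites (15 higher with DNMT3a siRNA, 9 lower) and 3 regions had an unadjusted p under 0.05. Without DNMT3b siRNA replicate 2 there were 13 such sites and 0 such regions, and over single libraries left out such regions numbered 0 to 5. The counts of sites called by other tools were 0 with limma, 0 with the quasi-binomial model and 7 with DESeq2 (5 higher, 2 lower). Groups did not overlap at 42 sites and 4 regions, or 13.5% and 15.4%, where chance gives 10% on average, and these shares were not tested against it. The sites with the smallest p did not pass after adjustment by edgeR (adjusted p = 0.231 for each). The CpG at offset 341 of Nppb_2 was at 60.6% ± 6.11 with DNMT3a siRNA and 38.9% ± 4.75 with DNMT3b siRNA (log2 odds ratio 1.28 ± 0.28 SE, 3664 to 5788 reads), beside 48.5% ± 6.99 with negative siRNA. That at offset 328 was at 51.3% ± 7.58 against 31.8% ± 2.66 (1.18 ± 0.28 SE, 5379 to 9000 reads), and that at offset 26 of Nppa_2 at 12.8% ± 3.64 against 6.28% ± 0.60 (1.10 ± 0.25 SE). Adjusted over the list alone, edgeR called 4 natriuretic peptide sites, all higher (smallest adjusted p 0.0271), against 0 over all sites. They were these 3 and offset 381 of Nppb_2, at 34.2% ± 8.13 against 18.2% ± 3.10, named after its values were seen. Offsets 328, 341 and 381 lie in the single amplicon Nppb_2, and sites of an amplicon are not independent. The remaining tested sites of Nppb_2 were at 66.6% against 60.1%, 72.9% against 76.6% and 90.2% against 92.9%, each without overlap. The direction was therefore not the same at all sites of that amplicon. In the other groups 0 sites were called over the list alone.

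Sarcomere genes averaged 51.6% ± 2.67 with DNMT3a siRNA and 51.0% ± 0.43 with DNMT3b siRNA (exact permutation p = 1.0), with 6 regions higher and 6 lower. CDK inhibitor genes averaged 26.9% ± 0.91 and 28.0% ± 2.23 (exact permutation p = 0.50), and transcription factor genes 15.6% ± 0.42 and 16.0% ± 0.078 (exact permutation p = 0.40). The mean over all regions differed by 0.80 points (exact permutation p = 0.90) and by -0.26 points without DNMT3a siRNA replicate 2.

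**Figure D3:**
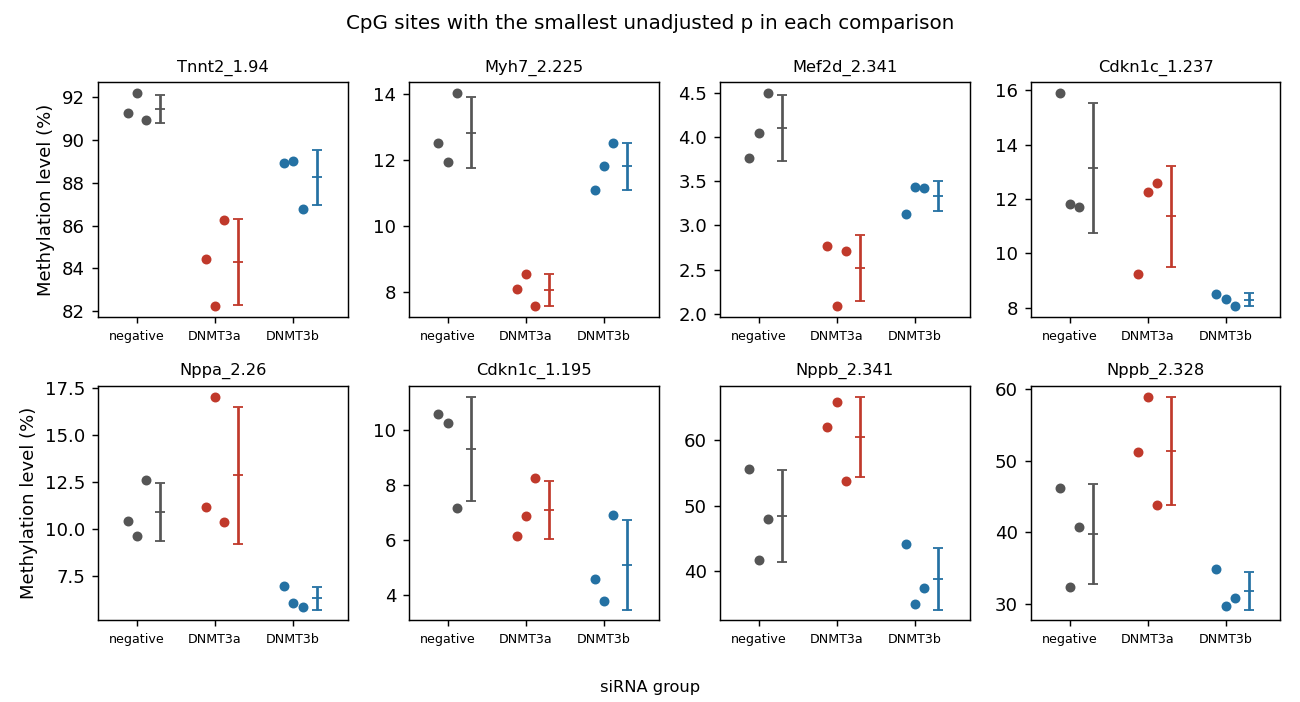
Methylation level (percent, vertical axis, scaled to each panel) of the 8 CpG sites with the smallest unadjusted p in the 3 comparisons, named by region and offset; points are libraries, with the mean and SD of 3 beside them. Tnnt2_1 at offset 94 and Myh7_2 at offset 225 are lowest with DNMT3a siRNA, and Nppa_2 at offset 26 is lowest with DNMT3b siRNA.

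Whether both knockdowns moved the same sites was examined across the 310 sites, which are not independent replicates. The changes against negative siRNA had a correlation of 0.204 and a covariance of 1.68. For a baseline, the deviations of all 9 libraries from their group means were shuffled and given random signs, and 3 served as shared controls. These simulated unchanged groups gave a mean correlation of 0.462 and a mean covariance of 2.83, because both changes share their controls. The observed covariance minus the simulated mean was -1.15, and the observed one lay within the range of 95% of simulated values, -1.02 to 8.33. The 3 controls are too few to be split, and overlap was not computed because edgeR called 0 of the 310 sites in both comparisons, with 36 and 29 at an unadjusted p under 0.05. DESeq2 called 4 sites for DNMT3a and 0 for DNMT3b siRNA.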

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

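DESeq2 on regions, the means without Myh7b_1 or without sites of wide spread, and paired differences of gene groups were chosen after seeing the data. Of 247 values recomputed for the counts, means and correlation, 231 were kept. Counts of calls were kept if they stayed at 0, means if they kept their sign, and the correlation if it changed little. Some could not differ, since paired means equal unpaired ones and a minimum difference cannot add to 0 calls. For the named sites and regions, 231 of 243 kept their direction and side of the threshold. The other 12 of those passed the threshold in the same direction. DESeq2 called 4 sites and 3 regions for DNMT3a against negative siRNA and 7 sites for DNMT3a against DNMT3b siRNA. Testing only the 177 sites between 2% and 98% gave 2 sites for DNMT3a against negative siRNA, at offsets 94 of Tnnt2_1 and 225 of Myh7_2 (lowest adjusted p by edgeR 0.0183, over all settings of that count 3.67e-06 to 0.472). That setting changed both the fit and the number of tests. Leaving out single libraries gave 0 to 3 regions for DNMT3a against negative siRNA, with 3 only without DNMT3a siRNA replicate 2, and 0 sites in each comparison. DNMT3a against DNMT3b siRNA changed sign in the mean over regions (-0.26 to 1.37 points) and in sarcomere genes (-0.93 to 1.5), among single libraries left out only without DNMT3a siRNA replicate 2.

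The near-zero difference of CDK inhibitor genes for DNMT3b siRNA changed sign with reads pooled over regions (-0.28 points), a coverage minimum of 100 (-0.041), sites weighted equally (-2.81) and without replicate 2 or 3 of either group (-0.77 to 1.32 over single libraries left out). For DNMT3a against DNMT3b siRNA, it did so with sites weighted equally (1.13), as did sarcomere genes without sites of wide spread (-0.19). For changes of sign the cause was not tested, and no exact p in this design can pass 0.05. The replicate number as a block gave 0 calls in each comparison, with 26, 18 and 20 sites at an unadjusted p under 0.05. Same-numbered libraries correlated at -0.24 to 0.54, over 0.1 in 7 of 9 pairs, and 4 of 9 libraries correlated best with their own number in both other groups. Over all 3 groups the numbers therefore did not match the libraries, which does not exclude a shared origin under other numbers. For DNMT3a against negative siRNA 1 of 3 same-numbered pairs exceeded 0.1. The closest pair there was negative siRNA replicate 2 with DNMT3a siRNA replicate 3 (0.79). Negative siRNA replicate 1 with DNMT3a siRNA replicate 1 (0.54) and negative siRNA replicate 3 with DNMT3a siRNA replicate 2 (0.29) were also positive. All other pairs between these groups were negative (-0.61 to -0.036). Pairing under other numbers can therefore not be ruled out, and no pairing of that kind was modelled. Within DNMT3b against negative siRNA (0.12 to 0.41) and DNMT3a against DNMT3b siRNA (0.15 to 0.36) all 3 pairs exceeded 0.1, so pairing there cannot be ruled out. With paired differences the means over regions were -1.86 points (exact sign-flip p = 0.25, the smallest possible with 3 pairs) and 0.80 points (p = 1.0) there, natriuretic peptide genes 4.76 points (p = 0.25) for DNMT3a against DNMT3b siRNA, and no call changed. Gaps of other lengths and summing both cytosines of a CpG were not run, because regions are named and a single strand is listed. Simulated recovery by edgeR at a log2 odds ratio of 1 was 45.7% over the 310 sites and 68.0% over those between 2% and 98%. Leaving out single libraries also moved other group means without changing their sign, to -0.24 to -2.33 points for CDK inhibitor and -0.17 to -0.57 for transcription factor genes in DNMT3a against DNMT3b siRNA. Against negative siRNA, transcription factor genes ranged over -0.39 to -0.88 for DNMT3a and -0.053 to -0.45 for DNMT3b siRNA.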

Other observations

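All explanations weighed here were written down, and their tests chosen, only after the results were seen, including the splits of libraries and the test of neighbouring bases. Cytosines outside CpG were mostly read as T, but 12 of 2195 with enough coverage carried C in over 10% of reads in the mean of all libraries. The highest was the CHG cytosine at offset 415 of Mef2d_1, at 84.3% ± 3.55 in negative, 86.2% ± 4.11 in DNMT3a and 87.8% ± 2.06 in DNMT3b siRNA (SD, n = 3 each, at least 81 reads). The CHH cytosine at offset 7 of Tnnc1_2 followed, at 68.3% ± 8.08, 74.3% ± 4.5 and 70.5% ± 6.86. All 12 lay near an end of their region, at offsets 6 to 12 or close to the last listed offset. Their lowest coverage in a library was 31 to 890 reads, where the median of a tested CpG was 7964. Whether these cytosines are methylated or reflect the amplicon ends was not tested. With edgeR, 0 of 2173 cytosines outside CpG were called in each comparison, with 150, 62 and 146 at an unadjusted p under 0.05. The CpG at offset 32 of Nppa_2 stood at 8.93% in negative siRNA replicate 2 and 8.92% in DNMT3a siRNA replicate 3, and at 0.639% to 1.26% in the other libraries. These libraries also deviated most alike from their group means among 27 pairs between groups, with a correlation of 0.794 across 177 sites.

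The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. With 0 sites called in the real split, all 10 splits gave as many by construction, so these counts decide nothing. The highest other counts were 0 for DNMT3a against negative, 0 for DNMT3b against negative and 2 for DNMT3a against DNMT3b siRNA. For regions, again 0 in the real split and all 10 as many, the highest others were 2, 0 and 1. At an unadjusted p under 0.05, the real splits gave 36, 29 and 24 sites and the highest others 33, 16 and 22.

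All 3 DNMT3b libraries had lower mean levels than all 3 negative libraries, by a difference of -1.86 points. The tables argue against a difference in incomplete conversion, since reads carrying C outside CpG differed by -0.0084 points. They also argue against a few sites of wide spread as the whole source, since -1.59 points were left without them. Over all regions, though not without Myh7b_1, excess conversion at an equal rate in every region is argued against as the whole source. It would need -4.31 points in the 3 regions over 80%, which differed by -1.51 (84.0% ± 0.99 against 85.5% ± 0.70, SD, n = 3 each). Their ratio to the mean over regions was higher in all 3 DNMT3b libraries (2.40 ± 0.019 against 2.32 ± 0.055, exact two-sided permutation p = 0.10, the smallest possible). Without Myh7b_1 the change needed was -3.27 points and these ratios overlapped (exact permutation p = 0.20). The argument thus rests on that region of wide spread, and excess conversion as the whole or a part of the difference stays open. The knockdown of DNMT3b stays open as a biological explanation, as do unequal amplification and a different share of cells other than cardiomyocytes left after the VCAM1 enrichment, none of which was tested.

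At 4 CpG sites the pooled SD within groups was over 10 points, where the median over the 310 sites was 1.09. They were offset 145 of Myh7b_1 (21.0 points), offset 195 of Tnnt2_1 (18.5), offset 49 of Tnni3_2 (12.9) and offset 374 of Cdkn1a_1 (12.1). At offset 145 of Myh7b_1 the levels were 67.0%, 13.7% and 31.9% in negative, 57.7%, 47.0% and 15.5% in DNMT3a, and 19.3%, 1.73% and 1.07% in DNMT3b siRNA libraries. A shift of the whole amplicon by a similar log odds is argued against, since the 17 other CpG sites of these regions followed with a median slope of 0.082. Smaller joint shifts stay open, since 15 of the 17 deviated in the same direction as the site. The closest were offsets 84 and 124 of Cdkn1a_1 and offset 161 of Myh7b_1, with Pearson correlations of deviations from group means of 0.926, 0.923 and 0.912 and Spearman correlations of 0.817, 0.983 and 0.833 (9 libraries). Without the 2 libraries farthest from the median, Pearson's r was 0.753, 0.859 and 0.863. By exact permutation within groups the Pearson p-values were 0.037, 0.0046 (the smallest possible) and 0.042, and the Spearman p-values 0.093, 0.0046 and 0.042. After adjustment over the 17 relations, 0 passed (lowest adjusted p 0.079). A base variant that differs between litters could give such sites, but the highest slope of 0.341 does not separate it from a change of methylation at the one CpG, and joint movement of neighbours is not what a variant alone would give. No biological explanation was tested.

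No reads were recorded in 4 regions. A duplicated reference sequence may account for Cdkn1b_2 and Cdkn1c_2, because 100% of their 104 listed cytosines match each other in offset and context, and reads matching both equally well would be ambiguous. Of the 141 cytosines listed for Cdkn1b_1, 54 match Cdkn1b_2 at a single shift. At most 8.97% of those of Cdkn1c_1 matched any other region. The sequence listed for both may thus be that of Cdkn1b, which would leave Cdkn1c without a second region of its own. For Cdkn1a_2 and Mef2c_2 a duplicated sequence is argued against, since at most 12.9% of their cytosines matched another region. Failed amplification there stays open and was not tested.

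A hypothesis was that the siRNAs would differ by the base after the CpG, because DNMT3A and DNMT3B may prefer different neighbouring bases. The level of the 97 sites followed by C or T relative to the 80 followed by A or G, within regions, was -0.15 ± 0.24 points with DNMT3a siRNA and -0.048 ± 0.16 with DNMT3b siRNA (SD, n = 3 each). The difference of -0.10 points was smaller than the spread (exact two-sided permutation p = 0.60, smallest possible 0.10), so these libraries do not decide it.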
